A study of Mus musculus with 20 samples.

How the data were processed

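Total RNA of the femoral shaft of 5-week-old mice was measured on 20 Affymetrix mouse expression arrays, 5 each for normal males, Hyp males, normal females and Hyp females. Per the labels' protocols, both femora were freed of their ends and flushed with saline, RNA was extracted with TRIzol, equal amounts from 2 mice alike in genotype and sex were pooled, and 8 µg of purified RNA was converted to cDNA and biotin-labelled cRNA. The deposited signal intensity of each probe set is a linear value in units of fluorescence per the file headers, made with GCOS, the one processing tool that the submitters' notes name, without its version, settings or scaling target. The mean signal of each array, trimmed by 2% at each end, was 500.0 on each of the 20 arrays, so the arrays share one trimmed mean. The authors also deposited a ratio of the Hyp to the normal mean over 10 arrays each, a score per term of an analysis of variance (the F statistics of genotype, sex, their interaction and block), and detection calls and P classes as text. The deposited F statistics of genotype were recomputed from the linear signals of part of the probe sets, with a largest relative difference of 1.42e-07. The matrix of values and the authors' table hold identical signals for 45101 probe sets.

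Probe sets were named through the gene table given for the array: 34958 carry 1 gene symbol, 932 carry several and 9211 carry none. Symbols were checked against the RefSeq gene table of assembly GRCm38.p6, used for names alone, and 0 changed through the gene identifier; of 333 symbols in the gene lists, 1 was matched through a synonym (Ankh, named Ank here). List members with no probe set named for them are not analysed here. No genome sequence was used, no coordinates are given, and the position of the Phex probes relative to the deleted part of the gene was not looked up.

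Signals were used as log2 of the signal plus a pseudocount of 16, without further normalization. Control probe sets (64) were left out, as were probe sets called present on fewer than 5 of the 20 arrays; 27141 were tested, 22456 of them with 1 symbol, for 12430 genes. One linear model held the 4 groups and the 5 series as a block, in limma 3.58.1 under R 4.3.3 with lmFit and eBayes, with 12 residual and 3.44 prior degrees of freedom. Contrasts were Hyp against normal over both sexes, within males and within females, the interaction of genotype and sex, and female against male over both genotypes. P values were 2-sided and adjusted by Benjamini and Hochberg over all probe sets tested, with a threshold of 0.05. The median SE of a log2 fold change was 0.11 over both sexes and 0.16 within a sex. Depth does not apply to array signals; where no array of a group called a probe set present, a fold is given as a bound against the lowest signal called present on each array, or as none where the probe set's own signal lies above that (Sost in Hyp males, the dimmer Phex probe set in Hyp females).

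The block follows the labels, which state that each replicate was matched for littermates and processed in parallel. Its presence in the signals was checked over the 30 pairs of arrays with the same number in different groups. The correlation of their deviations from the group means, taken across genes (which are not independent replicates), ran from -0.03 to 0.418. Its median was 0.215, against -0.07 for other pairs, and 12 of 20 arrays correlated best with their own number. Part of this likeness is wider than a series, as normal female 1 and Hyp male 2 correlated at 0.357. The first principal component, with 22.7% of the variance, ran from -52.5 to 7.86 in series 1 and 2. In series 3 to 5 it ran from 5.21 to 35.0, so the check does not part single series from these 2 sets.

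Gene lists were tested with limma's camera with a preset correlation between genes of 0.01, with an estimated correlation, and with fry, whose p asks whether a list's genes move on balance one way without comparing them with other genes. Each gene was represented by its probe set with the highest mean log2 signal, and p was adjusted over 24 lists: 12 of pathways and bone cells and 12 of markers of other cell types. They were osteocyte, osteoblast and bone matrix, mineralization and phosphate handling, FGF23 and vitamin D, osteoclast, Wnt and RANKL, proteases and convertases, glycolysis, oxidative phosphorylation, cell cycle, interferon response, sex-linked genes, skeletal muscle, erythroid, neutrophil, B lymphocyte, T and NK lymphocyte, monocyte and macrophage, megakaryocyte, adipocyte, cartilage, endothelial, tendon and fibrous tissue, and nerve and Schwann cell. Of the 12 osteocyte genes measured, 6 are in another list too, as are 4 of the 10 mineralization genes, while erythroid, megakaryocyte, endothelial, cell cycle and interferon lists share 0 members with others. An exact 2-sided sign-flip test of the mean shift of a list over the 10 pairs, Phex left out, was added after the data were seen; its 1024 flips give a smallest p of 0.00195. Single values between groups of 5 were compared by exact 2-sided permutation over 252 splits, which ignore the series.

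Comparisons, lists, alternatives and the rule for the genes named were fixed before the data were examined, apart from those said to be added later. The rule names Phex, the 10 largest rises and 10 largest falls over both sexes among called genes that moved the same way in at least 9 of 10 pairs, the 5 largest of each direction within a sex with 5 of 5 pairs, the 5 smallest p of the interaction, the 10 largest of each direction between the sexes, up to 4 members per list by smallest p, and Fgf23, Dmp1, Mepe, Sost, Cyp27b1, Pcsk2 and Scg5 where measured. Alternatives were pseudocounts of 1 and 64, quantile normalization, median centring, no filter, a stricter filter, no block, an intensity trend, robust eBayes, arrayWeights, the mean of all probe sets of a gene, the 2 groups of a sex alone, and each series and each array left out in turn. Added later were series 3 to 5 alone, the Hyp male arrays of series 1 and 2 left out, the actin 3′/5′ ratio as a covariate, the osteocyte list without Phex and the other Phex probe set. On simulated data with 200 changed probe sets among 27141, 90% of 2-fold changes were found for Hyp against normal over both sexes, 78% in males, 74% in females, 52% for the interaction and 100% between the sexes, with 11, 8, 6, 12 and 12 false calls. The simulated noise was independent between probe sets and the planted changes reached 4-fold, so these shares need not hold for the measured data. With 24 lists over 12430 genes, 0 lists passed when none was shifted. When the osteocyte list was shifted by 0.5, 2 passed, that list with a limma camera adjusted p of 2.34e-18 and 1 other. Of the 12 osteocyte genes, 6 are in other lists and were shifted there too, so the other pass need not be a false call. On the measured data, by contrast, swaps of Hyp and normal within pairs gave a median of 8 lists past the threshold with the preset correlation. Figures and tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.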

Results

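Gene expression was measured in the femoral shaft of 5-week-old C57BL/6J mice that carried the Hyp mutation and of their normal littermates, on 20 Affymetrix arrays. Hyp removes the 3′ end of Phex, an X-linked gene for a cell-surface endopeptidase of osteoblasts and osteocytes, and is the mouse counterpart of human X-linked hypophosphatemia, in which the kidney wastes phosphate and bone mineralizes poorly. The 4 groups were normal males, hemizygous Hyp males, normal females and heterozygous Hyp females, with 5 arrays in each. RNA of 2 mice alike in genotype and sex was pooled for each array, so the arrays stand for 40 mice. Each of the 5 series held 1 array per group, from littermates processed side by side, which gave 10 same-sex pairs of a Hyp and a normal array. Marrow had been flushed from the shafts with saline as far as possible. Between 49.3% and 56.9% of the 45101 probe sets were called present on an array. Arrays give no count depth, and their number limits the precision of each value.

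RNA quality differed between the genotypes on 1 of the 2 measures read from the control probe sets. The actin 3′/5′ signal ratio averaged 1.59 ± 0.12 (SD, n = 5) in normal males, 1.78 ± 0.09 in Hyp males, 1.5 ± 0.079 in normal females and 1.62 ± 0.065 in Hyp females. Its log2 value was higher in Hyp by 0.14 ± 0.09 (SD, n = 10 pairs), in 9 of 10 pairs, with a 2-sided exact sign-flip p of 0.00391. The Gapdh 3′/5′ ratio differed by 0.06 ± 0.17 on the log2 scale, upward in 8 of 10 pairs (exact p = 0.258).

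The comparison of Hyp with normal littermates over both sexes asks which transcripts of the shaft go with the mutation. The signal of Phex itself, read by its brightest probe set, showed the largest change. Hyp removes the 3′ end of the gene, and the position of the probes was not looked up. Here and below, loss of the probes' target therefore cannot be told apart from less transcript. The mean signal of Phex was 3411 ± 710.2 (SD, n = 5) in normal males and 31 ± 18.4 in Hyp males, where 0 of 5 arrays called it present. In females it was 4419.6 ± 1042 in normal and 725 ± 209 in Hyp mice, with a present call on 5 of 5 Hyp arrays. The fitted log2 change over both sexes was -4.45 ± 0.16 (SE), down in 10 of 10 pairs (limma adjusted p = 3.03e-10). As Hyp males lie at background, its size depends on the pseudocount, with -4.86 for a pseudocount of 1 and -3.86 for 64.

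Transcripts of osteocytes, the cells embedded in bone matrix, fell as a group in Hyp. Of the 12 members measured, 5 fell over all probe sets tested and 10 fell when adjusted over the list alone, and 0 had a positive fold change. Sost, which encodes the Wnt inhibitor sclerostin, fell by 1.31 ± 0.18 (SE) on the log2 scale in 10 of 10 pairs (limma adjusted p = 0.0031). Its mean signal was 340.1 ± 77.8 and 346 ± 124 (SD, n = 5) in normal males and females, against 129.7 ± 53.5 and 129 ± 18.3 in Hyp. As 0 of 5 Hyp male arrays called Sost present, the size of the fitted change rests in part on signals not above background, and none is given for males alone. Dkk1, another secreted Wnt inhibitor, fell by 1.27 ± 0.18 in 10 of 10 pairs (limma adjusted p = 0.00448). Dmp1, a matrix protein whose loss causes a recessive form of hypophosphatemic rickets, fell by 0.79 ± 0.15 in 10 of 10 pairs (limma adjusted p = 0.0156), and its 2 other probe sets in the fit passed the test too. Pdpn, a surface protein of young osteocytes, fell by 0.64 ± 0.12 in 9 of 10 pairs (limma adjusted p = 0.013). The call was lost in 0 of 25 repeats with a series or array left out for Sost, 1 for Dkk1, 3 for Dmp1 and 3 for Pdpn. For Mepe, a phosphoprotein of bone matrix, the log2 fold change was -0.75 ± 0.20 and missed the threshold (limma adjusted p = 0.0561). Fgf23, the phosphate-lowering hormone of osteocytes, did not pass either, at -0.09 ± 0.14 (limma adjusted p = 0.775), and the 95% interval of its fold ran from 0.762 to 1.16. Its mean signal lay between 127 and 144 in the 4 groups, with 5, 4, 5 and 3 present calls of 5 in the order of the groups above. As this signal is low and not called present on each array, the interval describes the probe signal. It need not bound the fold of the Fgf23 transcript. The median log2 fold change of the osteocyte list was -0.54 (limma camera adjusted p = 1.31e-11; adjusted p = 0.0941 with an estimated correlation), and without Phex it was -0.43. In an exact sign-flip test of the pairs, chosen after the data were seen and run without Phex, the list shifted by -0.58 ± 0.37 (SD, n = 10), down in 10 of 10 pairs, with p = 0.0156 after adjustment over the 24 lists. With the actin ratio as a covariate, also added after the data were seen, the SE of a gene grew 1.76-fold. Sost then stood at -1.21 ± 0.31, Dkk1 at -1.24 ± 0.31, Dmp1 at -0.76 ± 0.26 and Mepe at -0.48 ± 0.34, and Phex was the only probe set called.

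**Figure D1:**
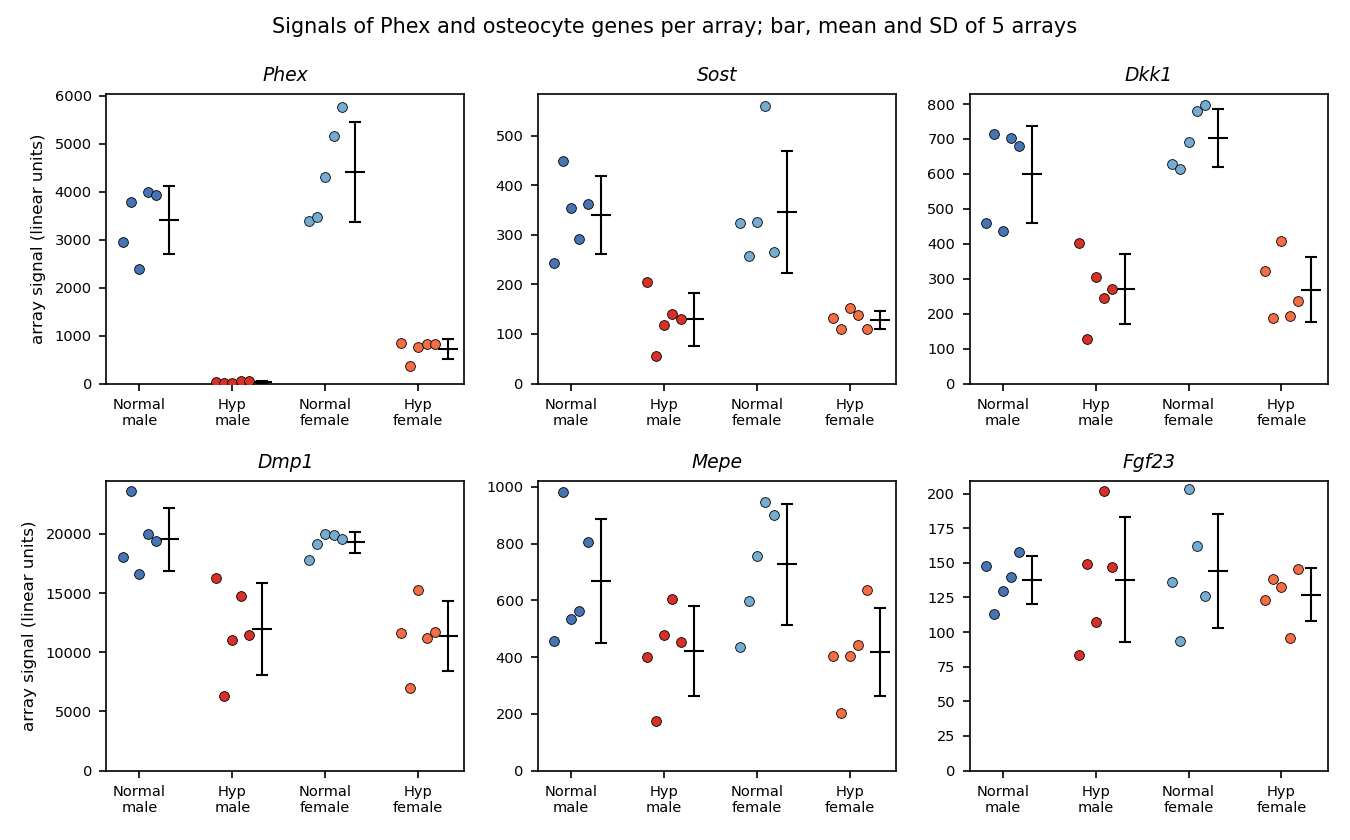
Array signal in linear units for Phex and 5 further osteocyte genes, with 1 point per array in each of the 4 groups and the mean and SD of 5 arrays as a bar. Phex lies at 31 ± 18.4 in Hyp males and 725 ± 209 in Hyp females, and Fgf23 means lie between 127 and 144.

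Outside that list, A2m, the broad protease inhibitor alpha-2-macroglobulin, fell by 1.47 ± 0.29 on the log2 scale in 9 of 10 pairs (limma adjusted p = 0.0185). Cpz, a secreted carboxypeptidase that binds Wnt proteins, fell by 1.17 ± 0.14 in 10 of 10 pairs, from 2117 ± 561 to 988.5 ± 207 in males and from 2799 ± 935 to 1120.0 ± 222 in females (SD, n = 5; limma adjusted p = 0.00144). Gal, the neuropeptide galanin, fell by 1.01 ± 0.17 and the proprotein convertase gene Pcsk6 by 0.95 ± 0.12. Ccn5, a matricellular protein, fell by 0.93 ± 0.14 and Lpar3, a receptor for lysophosphatidic acid, by 0.89 ± 0.11, each in 10 of 10 pairs. Fcgr2b, an inhibitory receptor for antibodies, fell by 1.01 ± 0.16 at its brightest probe set, while 2 of its 3 other probe sets in the fit had the opposite sign. The call was lost in 4 of 25 repeats with a series or array left out for A2m, 3 for Gal, 1 for Ccn5, 3 for Fcgr2b and 0 for Cpz, Pcsk6 and Lpar3.

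Fewer genes rose by as much. Prg2, the major basic protein of eosinophils, rose by 1.41 ± 0.19 in 10 of 10 pairs (limma adjusted p = 0.00387), from 160.2 ± 67.7 to 480.3 ± 206 in males and from 96 ± 33.3 to 260.4 ± 50.4 in females (SD, n = 5). H2az1, a histone variant, rose by 0.74 ± 0.09 in 10 of 10 pairs (limma adjusted p = 0.00206). The other named rises were Chd7 at 0.86, Mfsd2b at 0.74, Malat1 at 0.72, Prom1 at 0.72, Diaph3 at 0.71, Tlr13 at 0.70, Cit at 0.70 and Gja4 at 0.69, with limma adjusted p between 0.0109 for Gja4 and 0.0485 for Diaph3. With a series or array left out, the call was lost in 0 of 25 repeats for Prg2 and H2az1, 15 for Chd7, 14 for Mfsd2b, 5 for Malat1, 16 for Prom1, 21 for Diaph3, 4 for Tlr13, 3 for Cit and 2 for Gja4. Gja4 encodes a connexin of arterial endothelium, and Cit and Diaph3 encode proteins of cell division.

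**Figure D2:**
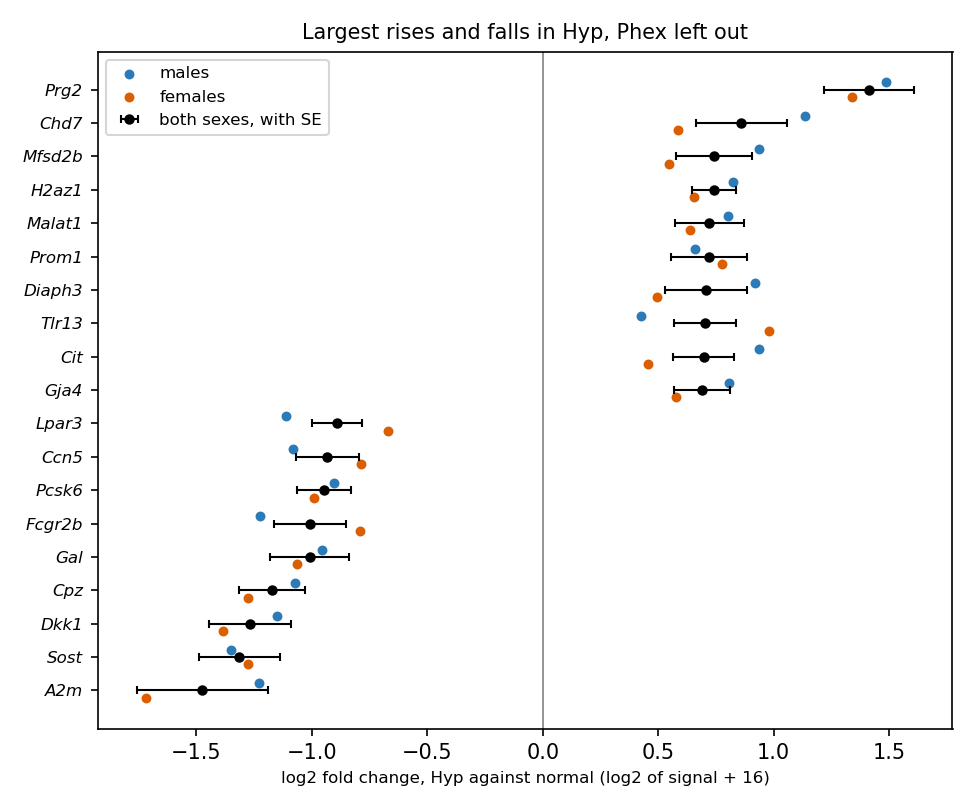
Log2 fold change of Hyp against normal for the 10 largest rises and the 9 largest falls after Phex, with the estimate over both sexes and its SE in black and the estimates within males and within females in colour. The values run from -1.47 for A2m to 1.41 for Prg2, and each gene has the same sign in both sexes, with Sost not above background in Hyp males.

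Genes of mineralization and phosphate handling fell as a group, with a median of -0.13. Of the 10 measured, 3 fell, Dmp1, Smpd3 and Ank, and adjusted over the list alone 4 fell and 1 rose. Smpd3, a sphingomyelinase needed for normal mineralization, fell by 0.70 ± 0.13 (limma adjusted p = 0.014), and Ank, which exports pyrophosphate, by 0.44 ± 0.07 in 10 of 10 pairs (limma adjusted p = 0.0101). The list gave a limma camera adjusted p of 0.00561 and an adjusted p of 0.355 with an estimated correlation, and by exact sign flips it shifted by -0.26 ± 0.22 (SD, n = 10), down in 9 of 10 pairs (adjusted p = 0.0234). Its median was -0.047 without replicate 2 and -0.21 without replicate 3, and it passed in both. In the list of Wnt and RANKL signalling, 3 of 16 fell, Sost, Dkk1 and Ccn4, and 4 fell when adjusted over the list alone. Ccn4, a Wnt-induced matricellular protein, fell by 0.60 ± 0.13, and Sfrp4, a Wnt antagonist, was at -0.45 (limma adjusted p = 0.0877). The list median was -0.14, with a limma camera adjusted p of 0.00532, an adjusted p of 0.355 with an estimated correlation, and an adjusted exact p of 0.0469, down in 8 of 10 pairs. Repeats with a series or array left out lost the call in 3 of 25 for Smpd3, 2 for Ank and 8 for Ccn4. The median of the Wnt list was -0.069 without replicate 4 and -0.094 without Normal male replicate 2, and the list passed in both. Sost and Dkk1 belong to the osteocyte list as well, and Dmp1 and Mepe are shared between osteocyte and mineralization lists. Dmp1 and Mepe, at -0.79 and -0.75, lay well below the mean shift of the mineralization list. Sost and Dkk1, at -1.31 and -1.27, lay well below that of the Wnt list, -0.29. The passes of these lists are therefore not independent of the fall of osteocyte genes.

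Osteoblast and bone matrix genes showed a smaller fall than osteocyte genes. Ifitm5, a membrane protein of osteoblasts, fell by 0.87 ± 0.14 (limma adjusted p = 0.00903) and Lox, which crosslinks collagen, by 0.54 ± 0.13 (limma adjusted p = 0.0435), the 2 of 18 members that passed, or 3 adjusted over the list alone. Omd, a keratan sulfate proteoglycan of bone, was at -0.34 (limma adjusted p = 0.0825). The list median was -0.12, with a limma camera adjusted p of 0.00728 and an adjusted p of 0.625 with an estimated correlation, and the exact test did not pass (adjusted p = 0.15). It no longer passed without replicate 2, with a median of -0.028, or without Hyp male replicate 2, with -0.062, and was at -0.19 without replicate 3. Of 15 proteases and convertases, 3 fell, Pcsk6, Pcsk5 and Ctsl, and adjusted over the list alone 4 fell and 1 rose. Pcsk5 fell by 0.49 and Ctsl by 0.28, while Ece1, an endothelin-converting peptidase, was at 0.40 (limma adjusted p = 0.0698). That list had a median of -0.15, a limma camera adjusted p of 0.00344, an adjusted p of 0.355 with an estimated correlation and an adjusted exact p of 0.0938. It was -0.076 and no longer passed without replicate 2, and was -0.088, -0.26 and -0.23 without Normal male replicate 2, replicate 3 and Normal male replicate 3. For osteoclasts, 0 of 15 markers passed, while adjusted over the list alone 4 fell and 1 rose. Ctsk, the collagen-degrading cathepsin of osteoclasts, was at -0.29, Src at -0.39 and Oscar at -0.33 (limma adjusted p = 0.118, 0.0877 and 0.0599). The osteoclast list median was -0.15, with a limma camera adjusted p of 0.0158, an adjusted p of 0.404 with an estimated correlation and an adjusted exact p of 0.129. The osteoclast list no longer passed without replicate 2 or 5, at -0.084 and -0.10, and was at -0.26, -0.086 and -0.0995 without replicate 3, Normal male replicate 2 and Hyp male replicate 5. In the list of FGF23, FGF signalling and vitamin D genes, 1 of 15 fell, Galnt3, the glycosyltransferase that protects FGF23 from cleavage, by 0.64 ± 0.15 (limma adjusted p = 0.0387), or 2 adjusted over the list alone. Etv5, a target of FGF receptor signalling, was at -0.41 (limma adjusted p = 0.0657). The list itself, with a median of -0.02, did not pass (limma camera adjusted p = 0.172). Repeats with a series or array left out lost the call in 3 of 25 for Ifitm5, 19 for Lox, 20 for Pcsk5, 15 for Ctsl and 18 for Galnt3. Cyp27b1, the renal enzyme that activates vitamin D, and Scg5, a chaperone of a proprotein convertase, were called present on 0 and 1 of 20 arrays and were not tested. Pcsk2 was not analysed here.

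Vessel markers were higher in Hyp. All 11 endothelial genes measured had a positive fold change, 3 rose over all probe sets tested (Flt1, Pecam1 and Cldn5) and 10 rose when adjusted over the list alone. Flt1, a receptor for VEGF, rose by 0.46 ± 0.09 in 10 of 10 pairs (limma adjusted p = 0.0175). Pecam1, an adhesion molecule of endothelial cell contacts, rose by 0.52 ± 0.12 and Cldn5, a tight-junction protein, by 0.44 ± 0.10, while Emcn, a sialomucin of capillaries and veins, was at 0.28 (limma adjusted p = 0.0648). Repeats with a series or array left out lost the call in 4 of 25 for Flt1, 20 for Pecam1 and 17 for Cldn5, and with the actin ratio as a covariate Flt1 stood at 0.35 ± 0.15 and Pecam1 at 0.37 ± 0.21, neither called. The median of the list was 0.42, with a limma camera adjusted p of 5.72e-09 and an adjusted p of 0.0941 with an estimated correlation. By exact sign flips it shifted by 0.40 ± 0.23 (SD, n = 10), up in 10 of 10 pairs (adjusted p = 0.0156). Interferon response genes shifted upward by 0.26 ± 0.11 (SD, n = 10), also in 10 of 10 pairs (adjusted exact p = 0.0156). Of the 11 measured, Ifit2, an antiviral protein, rose by 0.51 ± 0.11 (limma adjusted p = 0.028) as the 1 member called (lost in 10 of 25 such repeats), 4 rose when adjusted over the list alone, and Oasl2 was at 0.38 (limma adjusted p = 0.0879). Their list median was 0.28, with a limma camera adjusted p of 0.000791 and an adjusted p of 0.132 with an estimated correlation. The actin ratio, given above, was higher in Hyp in 9 of these 10 pairs.

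Cell cycle genes and markers of marrow cells that make red cells and platelets had positive medians over both sexes and passed with the preset correlation alone, with wide scatter between pairs. Within females, erythroid markers and cell cycle genes each had a median of 0.10 and did not pass (limma camera adjusted p = 0.355 and 0.2), upward in 2 of 5 pairs each. Female megakaryocyte markers had a median of 0.36, upward in 3 of 5 pairs (limma camera adjusted p = 0.0461; adjusted p = 0.685 with an estimated correlation), and that call was lost in 8 of 25 repeats with a series or array left out, with medians of 0.096 without replicate 1, 0.24 without Normal female replicate 1 and 0.13 without Hyp female replicate 1. In the cell cycle list, Tyms, which makes thymidylate for DNA synthesis, rose by 0.65 ± 0.13 in 10 of 10 pairs (limma adjusted p = 0.0205) as 1 of 17 members called (lost in 4 of 25 repeats with a series or array left out), and 12 rose when adjusted over the list alone. Mki67, Mcm6 and Aurka were at 0.59, 0.55 and 0.41 (limma adjusted p = 0.0653, 0.0528 and 0.06). That list had a median of 0.41, a limma camera adjusted p of 1.47e-07, an adjusted p of 0.355 with an estimated correlation and an adjusted exact p of 0.129, with 6 of 10 pairs upward. For erythroid markers, 0 of 8 passed over all probe sets and 7 rose when adjusted over the list alone, with Slc4a1, the anion exchanger of red cells, at 0.48 and Car1 at 0.62 (limma adjusted p = 0.0937 and 0.0909). The erythroid median was 0.47, with a limma camera adjusted p of 0.000147, an adjusted p of 0.355 with an estimated correlation and an adjusted exact p of 0.137, and it was 0.29 without replicate 1. Of 6 megakaryocyte markers, Gp5, a platelet glycoprotein, rose by a fitted 0.70 ± 0.17 (limma adjusted p = 0.0416; 0 of 5 normal female arrays called it present, and the call was lost in 17 of 25 repeats), 6 rose when adjusted over the list alone, and Itga2b, a platelet integrin, was at 0.62 (limma adjusted p = 0.0739). Their median was 0.64, with a limma camera adjusted p of 0.000174, an adjusted p of 0.355 with an estimated correlation and an adjusted exact p of 0.127. The Hyp male arrays of series 1 and 2 lay apart from the rest on the second principal component, at -57.6 and -46.2. The highest erythroid marker mean of the 20 arrays was that of series 1 and the highest megakaryocyte marker mean that of series 2 among these, as in the plot of marrow cell markers.

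**Figure D3:**
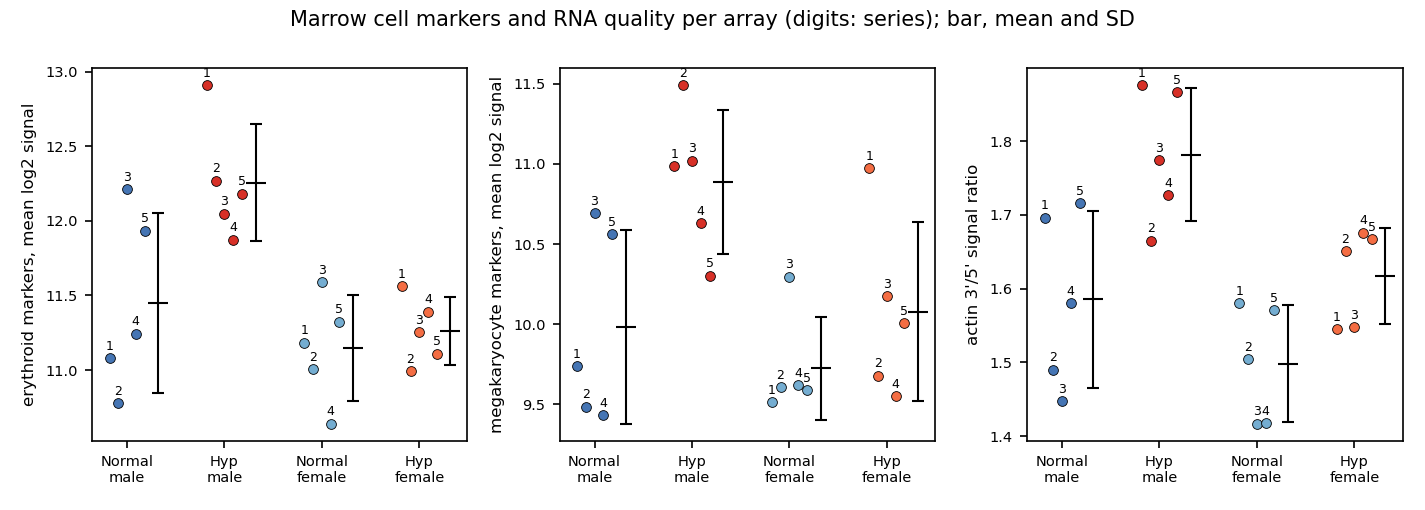
Mean log2 signal of the erythroid and megakaryocyte markers, and actin 3′/5′ signal ratio, with 1 point per array labelled by its series in each of the 4 groups and the mean and SD of 5 arrays as a bar. Erythroid means run from 10.64 to 12.91 and megakaryocyte means from 9.43 to 11.49, with the highest erythroid mean in the Hyp male array of series 1 and the highest megakaryocyte mean in that of series 2.

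The remaining 12 lists did not pass over both sexes. Their medians and limma camera adjusted p were 0.02 and 0.718 for glycolysis, -0.02 and 0.583 for oxidative phosphorylation, 0.05 and 0.185 for sex-linked genes, 0.06 and 0.185 for skeletal muscle, and 0.01 and 0.26 for neutrophils. They were -0.30 and 0.172 for B lymphocytes, 0.15 and 0.26 for T and NK lymphocytes, 0.07 and 0.288 for monocytes and macrophages, 0.10 and 0.431 for adipocytes, 0.02 and 0.908 for cartilage, -0.08 and 0.431 for tendon and fibrous tissue, and 0.14 and 0.555 for nerve and Schwann cells. Within the B lymphocyte list, the transcription factor Ebf1 was at 0.39 and the receptor chain Cd79a at -0.37 (limma adjusted p = 0.0529 and 0.102). For glycolysis and cartilage the median had the opposite sign to the mean, which was -0.02 and -0.004. Median, mean and test also differed in sign for adipocyte and cartilage lists within males, cartilage within females, 7 lists in the interaction of genotype and sex (osteocyte, FGF23, Wnt, protease, sex-linked, B lymphocyte and adipocyte), and sex-linked genes in females against males, and none of these passed. Kdm6a, an X-linked histone demethylase, rose by 0.45 ± 0.11 in 10 of 10 pairs (limma adjusted p = 0.0432), the 1 sex-linked gene called, and the call was lost in 21 of 25 repeats with a series or array left out.

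**Figure D4:**
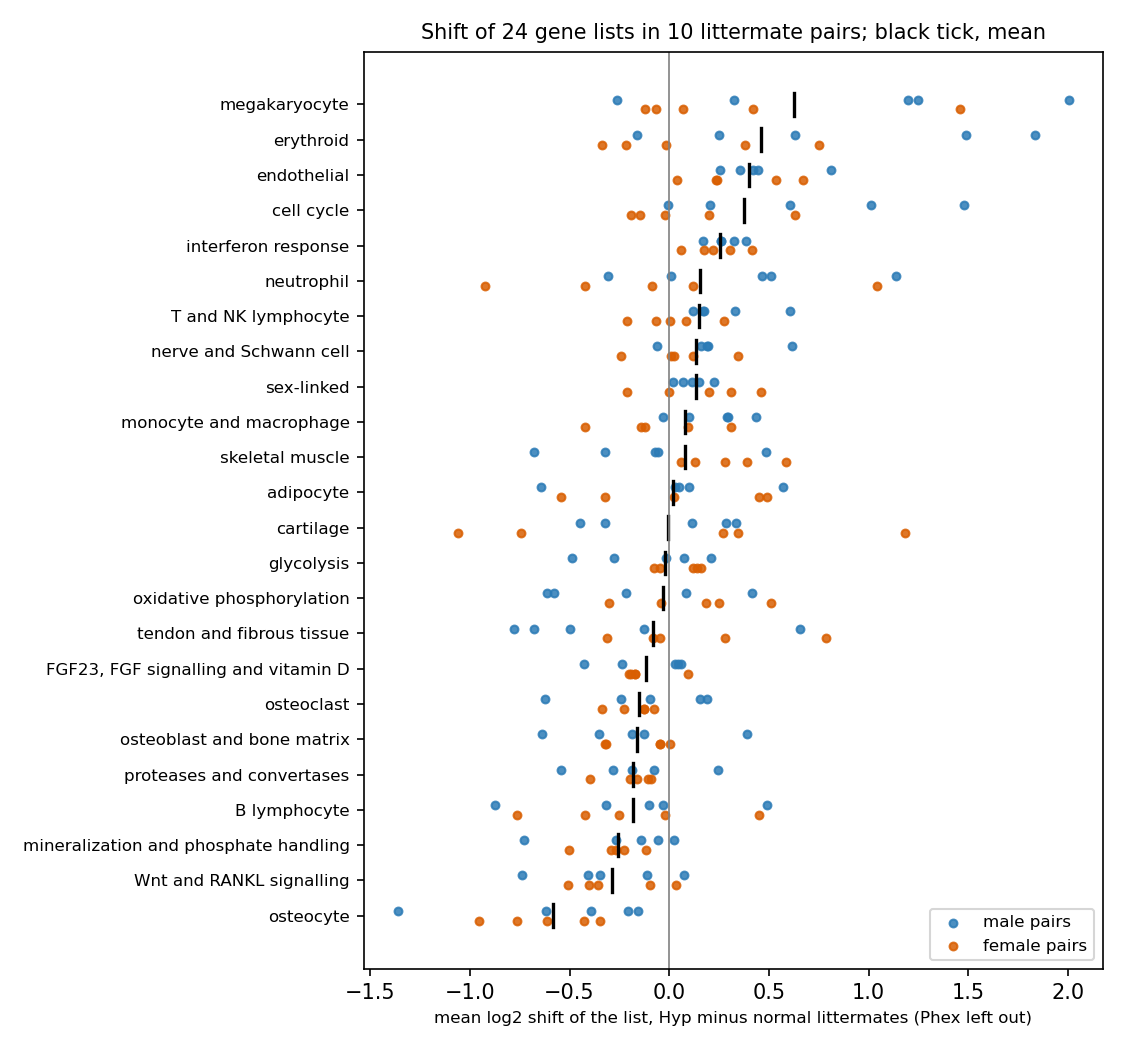
Mean log2 shift of each of the 24 gene lists between a Hyp and a normal array, with 1 point for each of the 10 littermate pairs, coloured by sex, a black tick for the mean, and Phex left out. Osteocyte genes are below 0 and endothelial and interferon response genes above 0 in 10 of 10 pairs.

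In the limma fit of 27141 probe sets, 647 passed an adjusted p of 0.05 for Hyp against normal over both sexes, 293 higher and 354 lower, for 476 genes. The balance turned without replicate 5, with 91 higher and 38 lower, and moved the other way with median centring, with 286 higher and 515 lower. Of the 647, 21 changed at least 2-fold, 4 higher and 17 lower. The authors' deposited analysis of variance, which is not adjusted for the number of tests, gives 6667 of 45101 probe sets a genotype P under 0.05, among them 647 of the 647. Of the 24 lists, 11 passed with the preset correlation, 5 up and 6 down, 0 passed with an estimated correlation (3 at an unadjusted p under 0.05), and 5 passed the exact sign-flip test. Swaps of Hyp and normal within pairs gave a median of 8 lists past the threshold with the preset correlation. The count was 317 with no replicate block, 148 with no filter, 81 without the Hyp male arrays of series 1 and 2, 1 in series 3 to 5 alone and 1 with the actin ratio as a covariate. It ranged from 20 without replicate 4 to 1343 without Normal male replicate 3.

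Within males, hemizygous Hyp mice were compared with normal males. The signal of Phex fell at least 103-fold, with 0 of 5 Hyp arrays above background, where loss of the probes' target cannot be told apart from less transcript. Of the other genes, Lpar3 fell by 1.11 ± 0.15 (SE) on the log2 scale (limma adjusted p = 0.0192), Ccn5 by 1.08 ± 0.19, Bcs1l, a chaperone of the respiratory chain, by 0.63 ± 0.11, and Map2k6, a kinase of the p38 pathway, by 0.63 ± 0.10. The largest rises were those of Xab2, a splicing factor, by 0.89 ± 0.16, Gm16793 by 0.86 ± 0.14, the lipid transporter gene Abca3 by 0.84 ± 0.15, H2az1 by 0.83 ± 0.13 and Ushbp1 by 0.67 ± 0.12, each in 5 of 5 pairs. With a series or array left out, the call was lost in 10 of 25 repeats for Lpar3, 22 for Ccn5, 22 for Bcs1l, 17 for Map2k6, 23 for Xab2, 20 for Gm16793, 23 for Abca3, 20 for H2az1, 22 for Ushbp1 and 0 for Phex. Osteocyte genes had a median of -0.51 in males, of 12 members 1, Phex itself, fell over all probe sets tested and 5 when adjusted over the list alone, and the list passed (limma camera adjusted p = 8.6e-08; adjusted p = 0.287 with an estimated correlation). This median rests in part on series 2, as it was -0.21 without replicate 2, -0.30 without Normal male replicate 2 and -0.32 without Hyp male replicate 2, and the list passed in each. It rests in part on Phex too, the mutated gene. With Phex left out, a test added after the data were seen, the male median was -0.33 (limma camera adjusted p = 2.9e-05). Of the 24 lists, 14 passed in males, 7 up and 7 down, and 0 with an estimated correlation. The largest upward medians were those of erythroid markers with 0.90 (limma camera adjusted p = 1.73e-06), megakaryocyte markers with 0.92 (limma camera adjusted p = 6.85e-05) and cell cycle genes with 0.72 (limma camera adjusted p = 1.19e-10), each with an adjusted p of 0.301 with an estimated correlation. Adjusted over the list alone, 8 of 8, 6 of 6 and 15 of 17 members rose. Endothelial markers had a median of 0.47 (limma camera adjusted p = 4.62e-07) and interferon response genes one of 0.25 (limma camera adjusted p = 0.00641), which ran from 0.13 to 0.36 with a series or array left out. Other marrow lists had smaller medians, with 0.28 for neutrophil and 0.24 for monocyte and macrophage markers (limma camera adjusted p = 0.0231 each), or did not pass, as B lymphocyte markers with -0.14. Over the 5 male pairs, erythroid markers rose further than B lymphocyte markers by more than the SD of the difference. Their differences from neutrophil, monocyte and macrophage, and T and NK markers lay within the SD. Downward, the medians were -0.16 for oxidative phosphorylation, -0.31 for tendon, -0.16 for osteoblast, -0.14 for mineralization, -0.15 for Wnt and RANKL and -0.16 for protease genes (limma camera adjusted p = 0.00998, 0.041, 0.0143, 0.0329, 0.0136 and 0.0231). With a series or array left out, the call was lost in 4 of 25 repeats for neutrophil, 3 for monocyte and macrophage, 5 for oxidative phosphorylation, 10 for tendon, 5 for osteoblast, 5 for mineralization, 2 for Wnt and RANKL and 5 for protease genes. The medians closest to 0 were 0.013 for neutrophil and 0.13 for monocyte and macrophage markers without Hyp male replicate 2, and -0.032, -0.043 and -0.029 for osteoblast, mineralization and protease genes without replicate 2. They were -0.053 for oxidative phosphorylation without replicate 1, -0.19 for tendon without Normal male replicate 3 and -0.088 for Wnt and RANKL without Hyp male replicate 4, where that list still passed. The erythroid median was 0.58 without replicate 1 and 0.48 without the Hyp male arrays of series 1 and 2. In all, 27 probe sets passed, 15 higher and 12 lower, for 17 genes, and 4866 had an unadjusted p under 0.05 where 1357 would by chance. The balance turned with median centring, with 19 higher and 23 lower, and without Hyp male replicate 3, with 6 and 10. It was 33 and 11 without Normal male replicate 5. The count fell to 2 with no replicate block and to 1 when only the 2 male groups were fitted, and it ranged from 1 without replicate 2 to 312 without Normal male replicate 3.

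Within females, heterozygous Hyp mice, whose cells express either the normal or the mutant X chromosome, were compared with normal females. Phex fell by 2.61 ± 0.22 (SE) on the log2 scale in 5 of 5 pairs (limma adjusted p = 0.000122) and was the only probe set called. Within pairs its signal in Hyp was 16.7% ± 5.4 (SD, n = 5) of normal, from 10.3% to 25%, with a 95% interval of the mean from 9.97% to 23.4%. The dimmer of the 2 Phex probe sets was called present on 0 of 5 Hyp female arrays and gives no share. Sost, Dkk1 and Dmp1 were at -1.28, -1.39 and -0.81 in females, Dkk1 and Dmp1 at -1.15 and -0.77 in males, and in neither sex alone did the 3 genes pass. Osteocyte genes had a median of -0.51 in females, and 10 of 12 fell when adjusted over the list alone (limma camera adjusted p = 1.91e-12; adjusted p = 0.152 with an estimated correlation). With Phex left out, the female median was -0.50 (limma camera adjusted p = 3.06e-09). Endothelial markers had a median of 0.36, with 4 of 11 rising when adjusted over the list alone (limma camera adjusted p = 7.31e-07; adjusted p = 0.182 with an estimated correlation). Skeletal muscle markers, with a median of 0.29 and a positive fold change for 13 of 13 members, were higher too (limma camera adjusted p = 6.79e-07; adjusted p = 0.474 with an estimated correlation). In all, 11 of 24 lists passed in females, 5 up and 6 down, and 0 with an estimated correlation. Besides megakaryocyte markers, given above, the others were interferon response with 0.29, oxidative phosphorylation with 0.14, mineralization with -0.16, osteoclast with -0.16, Wnt and RANKL with -0.14, protease with -0.18 and osteoblast genes with -0.08 (limma camera adjusted p = 0.00615, 0.0244, 0.00615, 0.0145, 0.0192, 0.00615 and 0.0487). With a series or array left out, the call was lost in 13 of 25 repeats for osteoblast, 8 for oxidative phosphorylation, 5 for Wnt and RANKL and 1 for interferon response genes. The mineralization median was -0.086 without replicate 2, and that of Wnt and RANKL -0.083 and -0.074 without replicates 4 and 5, -0.068 without Normal female replicate 5 and -0.080 without Hyp female replicate 2. Oxidative phosphorylation was at 0.24, 0.027 and 0.095 without replicates 1, 2 and 4, 0.24 and 0.071 without Normal female replicates 1 and 2, and 0.060 without Hyp female replicate 2. The osteoblast median ran from -0.15 without Hyp female replicate 3 to -0.021 without Normal female replicate 2. At an unadjusted p under 0.05 there were 2750 probe sets, against 1357 by chance. On simulated data, 74% of 2-fold and 36% of 1.5-fold changes were found in this comparison. That simulation held independent noise and called 154 probe sets, against 1 here. Its adjusted threshold was therefore looser, and the shares overstate what could be found on the measured arrays. With a pseudocount of 1, Phex in females no longer passed and 0 probe sets were called.

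The interaction of genotype and sex tests whether the change with Hyp differs between females and males. As Hyp males are hemizygous and Hyp females heterozygous, an effect of sex cannot be told apart from one of gene dose. Phex was the only probe set to pass, with a fitted difference of 3.66 ± 0.32 (SE) on the log2 scale (limma adjusted p = 0.000139). As Hyp males lie at background, its size is set by the pseudocount, with 4.44 for a pseudocount of 1 and 2.66 for 64, and is no measure of the difference in folds. In linear signal, the loss of Phex was 3380 ± 706 (SD, n = 5) in males and 3695 ± 954 in females, with an exact 2-sided permutation p of 0.571, whereas the log ratio gave an exact p of 0.00794. These permutations ran over 252 splits that ignore the series. The linear loss cannot exceed the normal signal, so its p does not test whether the signal left in Hyp differs between the sexes. The next smallest p belonged to Ccn2, Ky, Ccdc9 and Agr2, none of which passed. Ccn2, a matricellular protein, was at -0.57 in males and 0.23 in females, Ky at -0.58 and 0.56, Ccdc9 at 0.56 and -0.20, and Agr2 at 0.30 in males and at least 1.87-fold lower in Hyp females, where 0 of 5 arrays called it present. The shift with Hyp was lower in females than in males for 4 of 6 marrow lists and for cell cycle genes, with median differences of -0.74 for erythroid, -0.50 for megakaryocyte, -0.46 for neutrophil, -0.27 for monocyte and macrophage and -0.59 for cell cycle genes. It was higher in females for muscle, tendon and oxidative phosphorylation lists, by 0.43, 0.37 and 0.31. B lymphocyte and T and NK lists did not pass, at -0.0064 and -0.27 (limma camera adjusted p = 0.962 and 0.575). The 8 of 24 lists given first passed with the preset correlation, with limma camera adjusted p from 2.19e-08 for cell cycle to 0.0177 for megakaryocyte, and 0 passed with an estimated correlation, the lowest adjusted p being 0.771. With a series or array left out, megakaryocyte, neutrophil, tendon and monocyte lists lost the call in 10, 7, 7 and 4 of 25 repeats, and the other 4 in 0. The megakaryocyte median was -0.19 and -0.86 without replicates 2 and 5, -0.32 without Hyp male replicate 2, and -0.76 without Normal male replicate 5 or Hyp female replicate 1. The neutrophil median was -0.74, -0.14 and -0.19 without replicates 1, 2 and 4, -0.22 without Hyp male replicate 2, -0.30 without Normal female replicate 4, and -0.72, -0.27 and -0.31 without Hyp female replicates 1, 2 and 4. That of monocytes and macrophages was -0.17 without replicate 2 and -0.13 without Hyp female replicate 2, and that of tendon 0.11 and 0.64 without replicates 2 and 5. Each of these 4 lists lost the call at its median closest to 0. Unadjusted, 1798 probe sets had a p under 0.05, against 1357 by chance. In simulated data 52% of 2-fold differences were found. That simulation held independent noise and called 131 probe sets, against 1 here, so its adjusted threshold was looser and the share is an overstatement.

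Females were compared with males over both genotypes as a check of the sex labels and a measure of the sex difference. Xist, the RNA that silences an X chromosome, was higher in females by 6.48 ± 0.16 (SE) on the log2 scale in 10 of 10 pairs, and the X-linked genes Kdm6a and Eif2s3x by 0.77 ± 0.11 and 0.52 ± 0.07. The Y-linked genes Eif2s3y, Kdm5d and Uty were lower in females by at least 89.9-fold, 22-fold and 6.73-fold, against the lowest signal called present on each array. Outside the sex chromosomes, A2m was higher in females by 3.53 ± 0.29, Aldh1a2, which makes retinoic acid, by 1.24 ± 0.14 and Wnt4, a secreted Wnt protein, by 0.61 ± 0.11, while Gm16793 was at -0.56 and Dpep1, a membrane dipeptidase, at -0.51. The call was lost in 20 of 25 repeats with a series or array left out for Wnt4, 20 for Gm16793, 17 for Dpep1 and 1 for Kdm6a, and in 0 for the other genes named. Phex was higher in females in 9 of 10 pairs, with a fitted change of 2.20 ± 0.16, or 2.59 and 1.69 with pseudocounts of 1 and 64. Its mean signal was 3411 in normal males and 4420 in normal females, against 31 in Hyp males and 725 in Hyp females. The fitted change averages both genotypes and rests largely on the Hyp arrays, where males lie at background. It is therefore no measure of a sex difference in Phex among normal mice. Cell cycle, erythroid, neutrophil and megakaryocyte lists were lower in females, with medians of -0.47, -0.69, -0.48 and -0.56, and oxidative phosphorylation genes were higher, with 0.14. Their limma camera adjusted p ran from 2.76e-11 for cell cycle to 0.00247 for oxidative phosphorylation, and with an estimated correlation the adjusted p was 0.59 or more for each. The mean actin 3′/5′ ratio was lower in females too, at 1.498 against 1.586 in normal and 1.617 against 1.782 in Hyp mice. A part of RNA quality in these list differences is therefore not ruled out. Oxidative phosphorylation no longer passed without replicate 4 or Normal male replicate 5, at 0.12 and 0.089, and was at 0.0895 and 0.077 without Hyp male replicate 1 and Normal female replicate 1, and the neutrophil median was -0.31 without replicate 2. In all, 36 probe sets passed, 18 higher and 18 lower, for 17 genes, and the number was 26 with no replicate block and 153 without Normal male replicate 1. The even balance did not hold throughout, with 32 higher and 121 lower in that last repeat. It was 49 and 115 with an intensity trend, 8 and 21 with the actin ratio as a covariate, and 25 and 15 without Normal male replicate 3.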

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

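In this part, the tests of RNA quality, bone share, marrow left in the shafts, the Hyp male arrays of series 1 and 2, Hyp male RNA, the osteocyte fall beside Phex and the linear scale, and the swaps of male and female pairs within series, were chosen after the results were seen. The other counts over splits of the arrays were planned before the data were examined.

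For Hyp against normal over both sexes, 1 of 100 swaps within littermate pairs (of 512), the real one, called as many as the real 647 probe sets, and the highest other called 14. Chance is therefore unlikely for this count, though not all 512 swaps were run. The size of the count is less firm, with 20 without replicate 4, 1343 without Normal male replicate 3 and 1 with the actin ratio as a covariate. For the number of lists that passed, 11, chance is not excluded, since 20 of the 100 swaps gave as many, the highest other gave 14 and the median of the others was 8. Lists that passed with the preset correlation in males, females and the interaction were not set against such swaps. In males 2 of 100 splits of the 10 arrays (of 126) gave as many as the real 27, and the highest other called 212. That split set normal male arrays 1, 2, 3 and 4 with Hyp male array 3, parts 3 pairs where the real one parts 5, and points to a structure of the samples, whose source was not tested. The 16 swaps that part each male pair are too few for a share under 0.05, with 27 for the real one and 0 as the highest other (1 of 16 as large), and so are those of females, with 1 and 0 (1 of 16). Over all splits of the female arrays, 4 of 100 (of 126) gave as many as the real 1, with 1 as the highest other, and for the interaction 2 of 100 splits of the pairs gave as many as the real 1, with 1 as the highest other. These splits within a sex and of the pairs mostly part fewer pairs or series than the real ones, so chance is not called excluded from them. For the interaction, the 16 swaps of the male and the female pair within series are too few for a share under 0.05, with 1 for the real one and 0 as the highest other (1 of 16 as large). Between the sexes, 1 of 100 swaps within series, the real one, gave as many as the 36 probe sets, with 2 as the highest other. That count holds sex-linked genes such as Xist, which part by sex in any case, so the result checks the labels. It does not exclude chance for single genes outside the sex chromosomes, such as Wnt4.

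Transcripts of osteocytes were lower in Hyp, without Phex by a median log2 change of -0.43. With the actin 3′/5′ ratio as a covariate, the median was -0.45 (interquartile range of the members -0.72 to -0.32, a spread between genes and not an error of the median). The calls of single genes ended there, as SE grew 1.76-fold. The median did not shrink, but the ratio was itself higher in Hyp in 9 of 10 pairs and is a single measure. RNA quality is therefore not ruled out. Against a lower share of bone as the whole cause, the osteocyte list fell further than osteoblast and bone matrix genes by a difference of -0.42 ± 0.30 (SD, n = 10 pairs), in 9 of 10 pairs. This holds only as far as the osteoblast list tracks the share of bone. The osteoblast list shifted down too, in 8 of 10 pairs, so a contribution of bone share is not excluded. A first measure, endothelial minus B lymphocyte shift, did not decide, at 0.58 ± 0.64 with 8 of 10 pairs above 0. A candidate explanation is an effect of the mutation on osteocytes, and whether there may be fewer of them, less mature ones or less transcript in each stays open and untested.

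Erythroid and megakaryocyte markers were higher in Hyp males, with mean log2 signals of 12.26 ± 0.40 and 10.89 ± 0.45 (SD, n = 5) against 11.45 ± 0.60 and 9.98 ± 0.60 in normal males, in shafts that had been flushed. The 8 erythroid and 6 megakaryocyte markers measured are in no other list. Whole marrow left in the shafts cannot be told apart from a change in these cells, since erythroid markers rose further than B lymphocyte markers by 0.97 ± 0.54 (SD, n = 5 pairs), in 5 of 5 pairs, but further than neutrophil, monocyte and macrophage, and T and NK markers by 0.44 ± 0.58, 0.59 ± 0.84 and 0.53 ± 0.70, each within its SD. The part of the Hyp male arrays of series 1 and 2 cannot be told apart from that of the genotype, since the erythroid median was 0.48 (interquartile range 0.38 to 0.54) without them and 0.90 with them, and the bound set for the test lay inside that range. Uneven flushing of some marrow cells, a changed marrow in Hyp males and the sex of the mice or their dose of the mutation may each contribute, and were not tested. Sex and dose cannot be told apart here.

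Phex in Hyp females stood at 16.7% of normal, below the equal share of the normal allele that random X inactivation would leave, and its fitted log2 change differed from that in males by 3.66, a size set by the pseudocount, as Phex in Hyp males is not above background. Against Hyp male RNA in these samples, the Y-linked gene Eif2s3y reached at most 1.8% of its male mean of 2042. Against the fall of osteocyte transcripts as the whole cause, Phex divided by the median ratio of the other osteocyte genes was 23.2% ± 5.59 (SD, n = 5 pairs), with a 95% interval from 16.3% to 30.1%. Between the sexes, the loss of linear signal gave an exact permutation p of 0.571 and the log ratio one of 0.00794, by splits that ignore the series. The linear loss cannot exceed the normal signal, with means of 3411 in males and 4420 in females. Its p therefore cannot decide whether the sexes differ. The signal left in Hyp was 31 in males, with 0 of 5 present calls, and 725 in females, with 5 of 5. This difference cannot be told apart from gene dose, as Hyp males are hemizygous and Hyp females heterozygous. A lower level in cells that carry the normal allele, skewed inactivation and a probe response that is not linear at low signal may each contribute, and were not tested.

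Of 96 groups of 5 arrays tested, 9 held an array far from the other 4, where 4.8 would by chance at 1 in 20 groups. Normal male array 2 had a median signal of 143.2, against 154.8 to 158 in the others of its group. Mean log2 signals apart from their group were those of neutrophil markers in normal female array 2, 10.99 against 11.45 to 11.59, cell cycle genes in normal female array 3, 10.76 against 10.11 to 10.30, megakaryocyte markers in the same array, 10.30 against 9.52 to 9.62, and osteocyte genes without Phex in Hyp male array 2, 9.06 against 9.82 to 9.96. Single signals apart from their group were Phex in Hyp female array 2, 356.5 against 757.3 to 847.2, Sost in normal female array 4, 560.1 against 257.4 to 325.2, A2m in Hyp female array 5, 988.3 against 627.4 to 685.1, and Cpz in Hyp male array 2, 629.9 against 1008.5 to 1149.4.

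In the interaction of genotype and sex, 8 lists passed limma camera with the preset correlation, with medians of 0.31 for oxidative phosphorylation, 0.43 for skeletal muscle, 0.37 for tendon and fibrous tissue, -0.59 for cell cycle, -0.74 for erythroid, -0.46 for neutrophil, -0.27 for monocyte and macrophage and -0.50 for megakaryocyte genes. With an estimated correlation between genes their adjusted p lay between 0.771 and 0.854. Swaps of Hyp and normal within pairs gave a median of 8 lists past the threshold over both sexes with the preset correlation. No swaps were run for lists in the interaction. A difference between the sexes is therefore not shown for these lists, and sex could not be told apart from gene dose in it.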

How the results depend on the processing

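Chosen after the data were seen were the tests without the Hyp male arrays of series 1 and 2, in series 3 to 5 alone, with the actin ratio as a covariate, with the other Phex probe set and with the osteocyte list without Phex. With 5 arrays per group, 2 mice pooled in each, small changes lie near the limit of the test, and signal over background limits folds of genes not called present. The replicate block raised the count over both sexes from 317 to 647 and in males from 2 to 27, and between the sexes from 26 to 36, while 1 was called with and without it in females and for the interaction. Scaling moved the median of all genes by less than 0.1. Robust eBayes gives no value for the lists, and the authors' table, whose signals are identical, was not run as an alternative.

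For Hyp against normal over both sexes (647), the count was 148 with no filter, 1115 with a stricter one, 1269 with an intensity trend, 1431 with arrayWeights, 81 without the Hyp male arrays of series 1 and 2, 1 (3073 unadjusted) in series 3 to 5 alone and 1 (3307 unadjusted) with the actin ratio as a covariate. With median centring 35.7% of 801 called were higher, against 45.3% of 647, and with a series or array left out from 33.3% without replicate 1 to 70.5% without replicate 5, with more higher than lower also without Normal male 5, Hyp male 5, Normal female 2, Hyp female 2 or Hyp female 4. In males (27) it was 129 with a pseudocount of 64, 53 with quantile normalization, 42 with median centring, 4 with no filter, 197 with a stricter one, 429 with a trend, 104 with arrayWeights, 1 when only the 2 groups were fitted, 2 without the Hyp male arrays of series 1 and 2, 1 in series 3 to 5 alone and 2 with the actin ratio. In females (1) limma called 0 (2741 unadjusted) with a pseudocount of 1, 6 with 64, 3 with quantile normalization, 3 with median centring, 6 with the stricter filter, 25 with a trend and 36 with arrayWeights. Between the sexes (36) it was 59 with a pseudocount of 64, 164 with a trend, 57 with arrayWeights and 23 in series 3 to 5 alone. Of the lists, 11 or 12 passed in the settings run with the preset correlation and all arrays or the subsets above, 9 to 13 with a series or array left out, and 0 by limma camera with an estimated correlation (3 unadjusted). The filters change the number of probe sets tested, and the subsets and the covariate leave fewer degrees of freedom; for the other settings the cause was not tested.

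With 1 series or array left out, the count over both sexes ran from 20 to 1343. It was 147, 30, 20 and 129 without replicates 1, 2, 4 and 5, and 380, 269, 1343 and 241 without Normal male 1, 2, 3 and 4. It was 374 and 336 without Hyp male 1 and 2, 428, 392, 303 and 339 without Normal female 1, 2, 3 and 4, and 393, 293 and 311 without Hyp female 2, 4 and 5. In males it ran from 1 to 312, with 2, 1, 7, 2 and 2 without replicates 1 to 5, 3, 3, 312, 3 and 44 without Normal male 1 to 5, 2, 3, 16 and 2 without Hyp male 1 to 4, 6, 6, 7, 10 and 10 without Normal female 1 to 5, and 4, 6, 8 and 6 without Hyp female 2 to 5. In females it ran from 1 to 22, with 2 without replicate 3, Normal male 2, Hyp male 3 or Hyp female 3, 22 and 4 without Normal male 3 and 4, and 3 without Hyp male 5. The interaction count ran from 1 to 2, with 2 without Normal male 5 or Normal female 1, and that between the sexes from 26 to 153, with 153 without Normal male 1.

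Phex passed in its 5 comparisons under each setting but 1, females with a pseudocount of 1. Its percentage in Hyp females ran from 14.6 to 18.3 with a series left out and was 16.7 and 16.5 with quantile normalization and median centring, while the other probe set, present on 0 of 5 Hyp female arrays, gives no share. Over 88 values of single genes, 1623 of 2200 repeats with a series or array left out kept direction and side of the threshold, 545 no longer passed, 32 newly passed and 0 turned. Of 1148 under other settings, 872 kept both, 231 no longer passed, 44 newly passed and 1 turned, Fgf23 at 0.15 with the actin ratio. Of 62 list values, 1407 of 1550 repeats kept both, 109 no longer passed, 13 newly passed and 21 turned, and of 930 under other settings 814, 94, 7 and 15. Lists turned against all other genes, with these medians, without the Hyp male arrays of series 1 and 2 (adipocyte -0.033, neutrophil -0.10, osteoblast in males 0.032), in series 3 to 5 alone (FGF23 0.10, glycolysis 0.053, neutrophil -0.17, T and NK 0.041, tendon 0.054, osteoblast in males 0.043), with the actin ratio (B lymphocyte 0.25, glycolysis 0.0095, nerve 0.046), with no filter (cartilage 0.016), with the mean of all probe sets (cartilage -0.038) and with quantile normalization (skeletal muscle -0.052). With a series or array left out, medians of lists that turned ran from -0.084 to 0.13 for cartilage, -0.078 to 0.08 for glycolysis, -0.12 to 0.12 for neutrophil and -0.10 to 0.066 for oxidative phosphorylation genes. The cause of these turns was not tested.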

Other observations

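All tests of this part were chosen after the data were seen, and the genes named in it were picked after their values were seen.

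Genes of the secretory pathway stood out among the falls in Hyp over both sexes, and 4 lists of them were then written, with 2 lists for comparison. As the lists were chosen from these falls, their p restate what was seen on the same arrays and decide nothing. The median log2 fold change and limma camera adjusted p were -0.16 and 1.88e-06 for 22 genes of entry into the endoplasmic reticulum, -0.17 and 0.000286 for 12 of the COPII coat, -0.27 and 1.54e-05 for 9 of the COPI coat, and -0.12 and 0.00123 for 12 of the oligosaccharyltransferase. By exact sign flips the first 3 each had an adjusted p of 0.0156, down in 9 of 10 pairs, and the oligosaccharyltransferase one of 0.0445, down in 8 of 10 pairs. Ssr4 at -0.43 ± 0.08 (SE; limma adjusted p = 0.0107), Sec24d at -0.53 ± 0.10 (limma adjusted p = 0.0191) and Ostc at -0.54 ± 0.12 (limma adjusted p = 0.0367) had the smallest p of their lists, and none of the 3 passed in series 3 to 5 alone or with the actin ratio as a covariate. In all, 4 of 4 lists passed with the preset correlation and 0 of 4 with an estimated one, where the adjusted p was 0.133 for the first 3 and 0.242 for the last, and no cause was tested.

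For comparison, 14 genes of the proteasome core had a median of -0.02 (limma camera adjusted p = 0.966; adjusted exact p = 0.959). The 13 SR splicing proteins measured had a median of 0.18 (limma camera adjusted p = 0.00123; adjusted p = 0.186 with an estimated correlation; adjusted exact p = 0.0293), with Srrm2 at 0.41 ± 0.08 (SE; limma adjusted p = 0.024). Their median was 0.25 in males (limma camera adjusted p = 0.000857; adjusted p = 0.205 with an estimated correlation) and 0.07 in females, where they did not pass (limma camera adjusted p = 0.117).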
